A study of Malus domestica with 99 samples.

How the data were processed

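Fruit cortex of the apple cultivars Golden Delicious, Granny Smith and Fuji was profiled by RNA sequencing at harvest and at day 1, 7, 14 and 21 and 2 months after it. After harvest each cultivar was split into control fruit and fruit treated with 1-MCP, a gas that binds ethylene receptors and blocks the response to ethylene. The labels list 99 libraries in 33 groups of 3, which makes 11 groups per cultivar. Reads were aligned with STAR 2.5.1a and counted with HTSeq, per the submitters' processing notes, which name no genome build.

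The authors' deposited values are log2 group means, although the authors name the measure FPKM. Each column is 1 group, and its values are the mean over libraries of the log2 of a whole number, with a value of 0 entered as 0.5, so that -1 is the floor. This was worked out from low values (log2 under 2.5), which return to whole numbers within a relative tolerance of 0.0003 when 3 libraries are assumed in 31 columns and 2 libraries in 2 columns. Those 2 columns are Fuji control at day 14 and Fuji 1-MCP at 2 months, so 97 libraries entered the means. The quantiles of the columns nearly match one another, as after quantile normalization. The depth of the libraries is unknown, so no interval from counting was computed.

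The Golden Delicious and Granny Smith tables held 55627 transcript entries each. The Fuji table held the first 27230 of the same entries (49%), and the remainder could be examined in the other 2 cultivars alone. Entries are GenBank and RefSeq transcript identifiers. They were matched to a RefSeq gene table of the assembly GDT2T_hap1 for names alone, and 22330 identifiers (40.1%) matched when the version number was ignored. Of these, 504 also matched with the version, and the matches covered 19315 genes. A gene name rather than a locus number was found for 439 entries with 341 names, of which 226 entries were among those measured in Fuji. Where a name had several entries, only the entry with the highest mean level over all columns stood for the gene. The other entries of that name were not compared with it.

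Because every column is a group mean, no spread between replicate fruit could be computed, and tests planned per library before the data were examined were replaced. The replacements, their filter and their units were chosen after the tables were seen to hold group means, and after an exploratory run of the same contrasts. Entries were kept with log2 of at least 2 in at least 3 columns, which left 20999 entries in 3 tables and a further 21397 in 2 tables, 42396 in all. For entries in 3 tables, the difference between 1-MCP and control was computed per cultivar and tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options), with the 3 cultivars as the unit. The same was done for 1-MCP and control at day 21 against harvest. Within each cultivar, limma was run with days 7, 14 and 21 as the 3 units, and the differences of the 1-MCP effect between cultivars were tested day by day in the same way. For entries in 2 tables a call required passing in Golden Delicious and in Granny Smith with the same sign. This day-based rule was adopted after a fit with 2 cultivars as the unit had been seen. On simulated data with shuffled spread that fit recovered none of the changes and made 0 false calls. With model spread it recovered 3%, 49.3% and 86.6% of changes of log2 1, 2 and 4, with 20 false calls. The rule of passing in both cultivars was not itself simulated. The control time course was tested with an F-test in limma on cultivar and time over the 18 control columns. All tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05. The exception was camera from limma on sets of entries that changed after harvest, whose p-values were left unadjusted.

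These p-values weigh an effect against its spread between cultivars or between days, not between replicate fruit. Days of 1 cultivar share their fruit lot, so a lot difference between treated and control fruit would count as an effect of 1-MCP in the within-cultivar tests. A standard error (SE) given with a mean over cultivars has n = 3 cultivars.

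The tests across cultivars or days were tried on simulated data with 200 changed entries and normal noise. The data had many more calls, 7214 of 20999 entries for the mean of days 7, 14 and 21 across cultivars. Adjusted p depends on the number of changed entries, so the simulated shares recovered, here and above, need not be those of the data. The SD of an entry was either the observed SD of another entry, taken at random (shuffled spread), or drawn from the fitted model (model spread). For the mean of days 7, 14 and 21 across 3 cultivars, 20999 entries were used. There 0% of changes of log2 1, 41.8% of log2 2 and 71.6% of log2 4 were recovered with shuffled spread, with 2 false calls. With model spread the shares were 31.8%, 70.1% and 95.5%, with 1 false call. Tests over 3 days, from shuffled to model spread, recovered for changes of log2 4 62.7% to 94% in Golden Delicious, 62.7% to 92.5% in Granny Smith and 79.1% to 100% in Fuji. For log2 2 the shares were 35.8% to 65.7%, 28.4% to 53.7% and 59.7% to 79.1%, and for log2 1 they were 0% to 21.2%, 0% to 22.7% and 18.2% to 53%, with 0 to 11 false calls. Tests of cultivar differences recovered for log2 4 38.8% to 85.1% for Golden Delicious against Granny Smith, 73.1% to 94% for Golden Delicious against Fuji and 68.7% to 91% for Granny Smith against Fuji. For log2 2 the shares were 0% to 59.7%, 35.8% to 74.6% and 34.3% to 73.1%, and for log2 1 they were 0% to 13.6%, 0% to 51.5% and 0% to 36.4%, with 0 to 11 false calls. The time course test was tried with neither of these spreads, but with a fixed SD of 0.4 and the change placed at day 21 alone. Under that setting it recovered 31.8%, 100% and 100% of changes of log2 1, 2 and 4, with 5 false calls. Its recovery at the spread of the real data was not tested.

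Gene lists were made from gene symbols. They replaced planned lists of words and sequence motifs, which could not be filled because the tables carry neither descriptions nor sequences. The symbol lists were written before the values of their genes were seen, with 1 exception. CAS1 and CAS2 were moved to a list of their own after their values were seen, because the symbol is shared by cycloartenol synthase and cyanoalanine synthase. The lists covered ethylene synthesis, ethylene perception and signalling, ERF factors, other AP2-domain factors, Aux/IAA proteins, auxin response factors, auxin transport, cell wall, sugar and sorbitol, starch, lipoxygenases, terpenes and sterols, CAS, flavonoids, carotenoids, gibberellin, cytokinin, the GABA shunt, MADS, NAC, WRKY, heat shock factors, polyamine, allergens and defence, and phloem. A list's median was ranked against 10000 random lists of its size, in which each member was replaced by an entry of similar mean level. These entries were drawn independently, so the ranks take no account of correlation between list members. Lists with at least 5 members in 3 tables were tested with camera from limma, with its preset correlation and with an estimated correlation. List members past the threshold were also counted with p-values adjusted over the list alone.

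Genes were named by rule. Of named genes with a mean level of at least 5 on the linear scale, the 10 with the largest rise and the 10 with the largest fall were taken, among those past the threshold and of the same sign at days 7, 14 and 21 in every cultivar. Up to 4 genes past the threshold were added per list, 5 per direction for control at day 21 against harvest, and 5 per direction for each cultivar difference. At most 2 entries without a gene name were given per direction. A list member given as not past the threshold serves to complete its list. Changes are not given for groups in which a gene was listed at 0. The rule was adapted from the planned one, which asked for the same sign in every replicate.

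Alternatives were no filter, a stricter filter (log2 of at least 4), adding 4 on the linear scale, centring the differences on their median, leaving out each cultivar or each day, using the cultivar-by-day pairs or 2 cultivars as the unit, and leaving out day 14 in Fuji. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, fits used the package data.table (version 1.17.8), and plots used matplotlib 3.10.9. No column was left out.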

Results

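Transcript levels were measured by RNA sequencing in the fruit cortex of 3 apple cultivars, Golden Delicious, Granny Smith and Fuji, from harvest to 2 months later. The series concerns how ethylene and auxin act together in ripening after harvest, and its treated fruit received 1-MCP, which blocks the ethylene receptors. Each cultivar had 11 groups, namely harvest and then control and 1-MCP fruit at day 1, 7, 14 and 21 and at 2 months, with 3 libraries labelled per group. Values are the authors' group means on the log2 scale, so no spread between replicate fruit is given with any level. The depth of the libraries is unknown. Fuji values covered 49% of the transcript entries of the other cultivars, and where a gene lay outside that part its values are given for Golden Delicious and Granny Smith. A change is called here when the adjusted p from limma across the 3 cultivars was under 0.05, or, for genes without Fuji values, when it was under 0.05 across days 7, 14 and 21 in both remaining cultivars with the same sign.

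Several ripening genes were lower in 1-MCP than in control fruit through days 7, 14 and 21. The ACC oxidase ACO1, 3 ethylene receptors, 2 ERF factors, the polygalacturonase PG1, the xyloglucan enzyme XET01, the lipoxygenase LOX7a and the synthase of the scent compound alpha-farnesene all fell against control fruit. Over the same days 4 of 9 Aux/IAA genes, 2 of 3 auxin response factors, 3 of 4 starch genes and the transporters SUT1 and MdSOT3 were higher than in control fruit. The calls of the ERF factor ERF1 and the starch genes AMY10 and GBSSIa were lost whichever cultivar was left out. Among all entries, 3893 of 20999 with Fuji values and 3105 of 21397 without were called higher over these days. Camera found no shift in any list large enough for it. The direction was shared by the cultivars for most of the genes tested. Changes are given as log2 differences, negative where the level was lower. Unless a change after harvest is named, a gene that rose or fell did so in 1-MCP against control fruit, not over time.

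Across the 3 cultivars, 7214 of 20999 entries (34.4%) differed between 1-MCP and control fruit in the mean of days 7, 14 and 21. Of these, 3893 were higher and 3321 lower with 1-MCP, and 1603 and 1218 differed at least 2-fold. The sign was the same in all cultivars for 68.1% of the entries tested, where independent signs would give 25%. Leaving out Fuji lowered the number of calls to 2166. Among the 21397 entries without Fuji values, 3105 were higher and 2541 lower in both remaining cultivars, where independent calls would give 1029 and 758, and 119 had opposite signs; leaving out day 14 lowered the count of 5646 shared calls to 734, and having no filter on low values lowered it to 617.

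The steepest fall with a gene name was that of AFS1 (NM_001293893), the alpha-farnesene synthase, with a difference of -9.23 (SE 0.176, adjusted p 0.000667). The difference was -8.96 in Golden Delicious, -9.62 in Granny Smith and -9.13 in Fuji, and its level in 1-MCP fruit lay near the floor of the tables, so that the mean difference shrank to -7.66 with 4 added to the values. An entry without a gene name, AY787634, fell (-9.28, SE 0.151). ACO1 (NM_001294118), an ACC oxidase, fell (-6.96, SE 0.306, adjusted p 0.002). At day 21 its level was 15.65 in control and 10.04 in 1-MCP fruit of Golden Delicious, 13.77 and 6.03 in Granny Smith, and 13.98 and 6.38 in Fuji. ACO1 was the 1 gene tested in the list of ethylene synthesis. The RefSeq gene record behind its name also gives ETR1 as a synonym, and the first-listed name was kept. Of 8 genes of ethylene perception and signalling, 3 receptors fell and 5 genes were not called. ETR2 fell (-2.84, SE 0.181, adjusted p 0.00303), as did ERS1 (-3.05 in Golden Delicious and -2.88 in Granny Smith) and ETR5 (-2.20 and -1.90). ETR1, CTR1, EIN2 and EIL3 were among those not called. Both ERF genes tested were lower. ERF2 fell (-3.22 in Golden Delicious and -2.88 in Granny Smith), as did ERF1 (-0.45, adjusted p 0.049), a call lost when any 1 cultivar was left out (adjusted p 0.0579 to 0.168), when day 7 was left out (0.0699), without a filter (0.0848) and with 4 added to the values (0.0531).

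**Figure D1:**
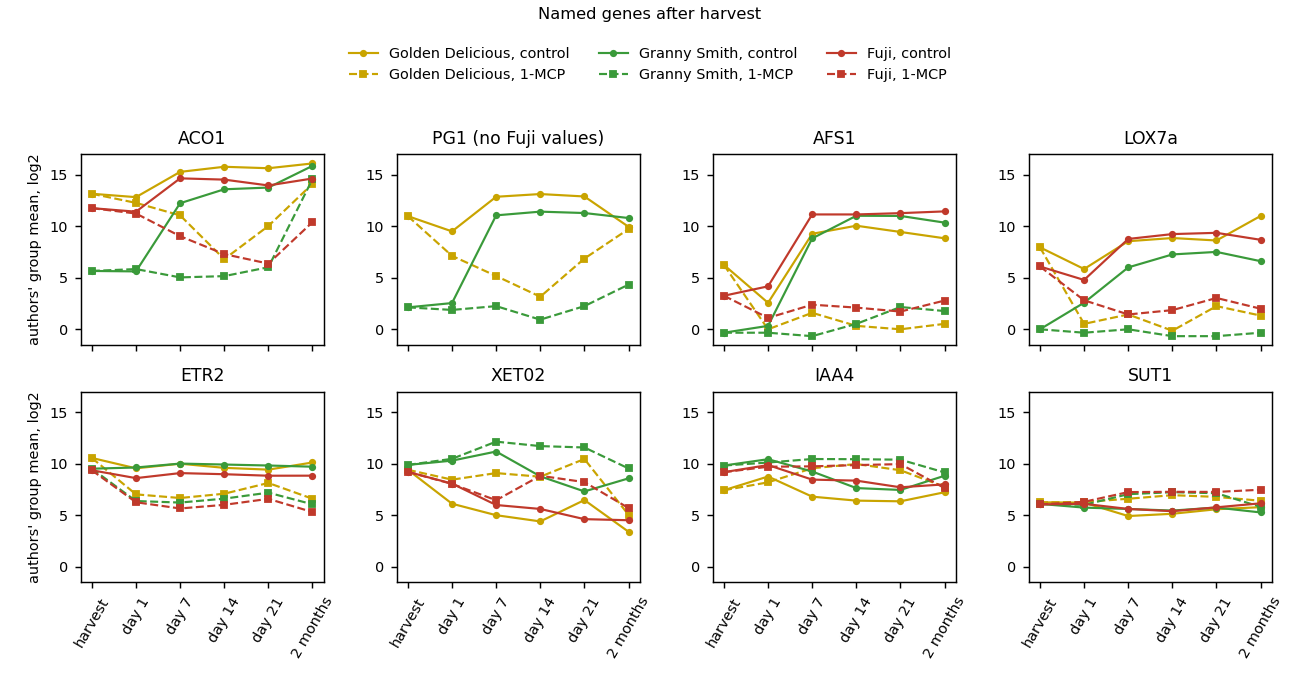
Authors' group means (log2, vertical axis) of 8 genes at harvest and at 5 times after it, with solid lines for control fruit, dashed lines for 1-MCP fruit and colours for cultivars. ACO1 separates by treatment in each cultivar from day 7, whereas ETR2 has already separated at day 1, with a mean difference of -2.71.

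Cell wall genes moved mainly down. Of 9 tested, 5 fell, 1 rose and 3 were not called, and the list median was -1.21 in Golden Delicious, -1.21 in Granny Smith and, over the 4 genes with Fuji values, -0.95 in Fuji, at or under the 1.4 percentile of random lists in each. PG1 (NM_001293928), a polygalacturonase, fell in Golden Delicious (-7.90, adjusted p 0.00271) and in Granny Smith (-9.45, adjusted p 0.000281). BGAL101, a beta-galactosidase, fell (-1.95, SE 0.327, adjusted p 0.0163), a call lost without Fuji (adjusted p 0.078). The xyloglucan enzyme gene XET01 fell (-7.72 in Golden Delicious and -6.05 in Fuji), and it was listed at 0 in Granny Smith 1-MCP fruit at days 14 and 21, so the size of its fall depends on the floor. Its relative XET02 (NM_001294113) went the other way and rose by 3.10 (SE 0.358, adjusted p 0.00796). The expansin gene EXP1 was lower (-2.996 in Golden Delicious and -2.27 in Granny Smith), and its difference in Granny Smith was not past the threshold (adjusted p 0.0582).

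Auxin genes rose in part. Of 9 Aux/IAA genes 4 rose and 5 were not called. Of the 7 with values in all cultivars, 3 passed over all entries and 3 adjusted over the list alone. Among genes with Fuji values in the other lists, adjusting over the list alone added 1 higher auxin response factor, 1 lower carotenoid gene, 1 higher gene of the GABA shunt and 1 higher WRKY gene, and changed no other count. With Fuji values the list of auxin response factors held 1 gene, so its p was in effect unadjusted. The carotenoid and GABA shunt lists held 2 each, so adjustment there was slight. IAA4 (NM_001300877) rose by 2.37 (SE 0.283, adjusted p 0.00845), with 3.11 in Golden Delicious, 2.32 in Granny Smith and 1.68 in Fuji. IAA11 rose by 2.03 (SE 0.374, adjusted p 0.02), IAA12 by 1.38 (SE 0.202, adjusted p 0.0123), and IAA2 by 1.10 and 0.99 in the cultivars with values. The calls of IAA11 and IAA12 were lost without Fuji (adjusted p 0.0728 and 0.0584), and that of IAA11 also without Granny Smith (0.0553). The median of the 9 Aux/IAA genes ranked at the 99.9 percentile of random lists in Golden Delicious and the 99.5 in Granny Smith, and that of the 7 with Fuji values at the 58.6 percentile in Fuji, so these ranks do not compare the cultivars. Over the 7 genes camera found no shift of the list (p 0.271 preset, 0.516 with estimated correlation). Of 3 auxin response factors, ARF2 rose by 1.78 and 2.18 and ARF3 by 1.49 and 0.81, while ARF1 was not called (0.48, adjusted p 0.0615). In auxin transport and binding, the efflux carrier gene PIN7 fell (-2.001 in Golden Delicious and -1.995 in Granny Smith) and 3 genes were not called, PIN10 among them (1.39 and 2.71).

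Sugar and starch genes were divided. Of 12 sugar and sorbitol genes 2 rose, 2 fell and 8 were not called. The sucrose transporter SUT1 (NM_001293880) rose by 1.59 (SE 0.089, adjusted p 0.0023), and the sorbitol transporter MdSOT3 by 4.09 in Golden Delicious and 2.88 in Granny Smith. The fructokinase FK fell (-0.68), as did SDH1, a sorbitol dehydrogenase (-0.64 and -1.14). Of 4 starch genes 3 rose and 1 was not called: GBSSIb by 1.60 and 1.08, AMY10 by 0.59 and GBSSIa by 0.50. Calls of AMY10 and GBSSIa did not outlast leaving out any 1 cultivar (adjusted p 0.0512 to 0.0781), and that of FK was lost without Granny Smith (0.058) or Fuji (0.0769). In the GABA shunt 2 of 3 genes rose, GAD2 by 1.91 and 2.26 and GABA-T2 by 1.44 (SE 0.165, adjusted p 0.00756), and GAD1 was not called.

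Of 7 lipoxygenase genes 2 fell, 1 rose and 4 were not called. LOX7a (NM_001294093) fell (-7.30, SE 0.164, adjusted p 0.000667) as did LOX5a (-1.41, SE 0.12), whereas LOX7c rose by 1.41 and 1.48. With 4 added to the values the difference of LOX7a shrank to -5.59, since its level in 1-MCP fruit was near the floor. AFS1 was the 1 of 4 terpene and sterol genes to be called. The carotenoid gene PSY2, a phytoene synthase, fell (-2.83, SE 0.21, adjusted p 0.00396), and the second gene of that list was not called. Of 8 flavonoid genes F3H fell (-2.43), MdF3H rose by 0.80 and 0.72, and 6 were not called, DFR among them (0.70 and 3.38). F3H lost its call without Golden Delicious (adjusted p 0.0577), without Fuji (0.103) or with 4 added to the values, which shrank the difference to -0.98 (0.0521). The allergen gene MALD1 (NM_001294363) fell (-6.24, SE 0.352, adjusted p 0.00266), and in its list of 4 allergen and defence genes VSP fell (-0.39 and -0.51). CAS2 fell (-6.04 in Golden Delicious and -7.01 in Granny Smith), as did CAS1 (-1.72, SE 0.126, adjusted p 0.00338). The symbol CAS is shared by more than 1 enzyme, and the gene table does not say which is meant.

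Regulators moved both ways. For comparison with the counts below, 34.4% of all entries with Fuji values were called in either direction. Of 13 MADS genes 4 rose and 9 were not called, with DAM2 up by 1.77 (SE 0.121, adjusted p 0.00303), AP1 by 1.09, MADS2 by 1.15 and 0.60, and MADS6 by 0.47. Of 13 NAC genes NAC10 rose by 5.51 in Golden Delicious and 1.90 in Granny Smith, NAC1 fell (-1.91, SE 0.195, adjusted p 0.00662), NAC3 fell (-0.71), and 10 were not called. Of 10 WRKY genes WRKY6 rose by 0.68, WRKY1 rose by 0.48, WRKY16 fell (-0.69), and 7 were not called. Of 7 AP2-domain genes besides ERF1 and ERF2, AP2D42 rose by 0.62, AP2D11 fell (-0.79), and 5 were not called. CYCD3, a D-type cyclin, rose by 3.30 (SE 0.559, adjusted p 0.0165), or by 2.41 with 4 added to the values. The zinc-finger gene Col1 rose by 2.12 and 2.57 and the homeobox gene HD14 by 2.65 and 1.83, while HD1 fell (-1.47). RA was listed at 0 in Golden Delicious control fruit at day 7, so no change is given for it, although it was called higher. Calls lost when 1 cultivar was left out included those of CYCD3 (adjusted p 0.0719 without Golden Delicious, 0.0741 without Granny Smith), AP1 (0.0514 without Granny Smith), and MADS6, WRKY6, WRKY16 and AP2D11 whichever cultivar was left out (0.0552 to 0.167), and those of WRKY1 and AP2D42 without Golden Delicious or Fuji (0.0815 to 0.19). WRKY6, AP2D11 and AP2D42 also lost theirs without a filter (0.0525 to 0.0894), WRKY6 and AP2D42 without day 7 or day 14 (0.0531 to 0.0684), and AP2D42 with 4 added (0.0504).

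In the remaining lists few genes were called. CHK3b rose by 0.585 among 3 cytokinin genes and MdSPDS1 by 0.40 among 3 polyamine genes, with 2 in each not called. Both calls were lost without Granny Smith or Fuji (adjusted p 0.0691 to 0.117), and that of MdSPDS1 also without Golden Delicious (0.116) or day 7 (0.0888). Among 4 gibberellin genes, 4 heat shock factors and 2 phloem genes no call was made by the limma rule. In the 6 lists with enough members, camera gave adjusted p of 0.462 to 0.5 with the preset and 0.562 with the estimated correlation. Among entries without a gene name, XM_008361468 (LOC103423394) rose by 5.73 (SE 0.77) and XM_008391644 (LOC103452146) by 5.61 (SE 0.851).

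**Figure D2:**
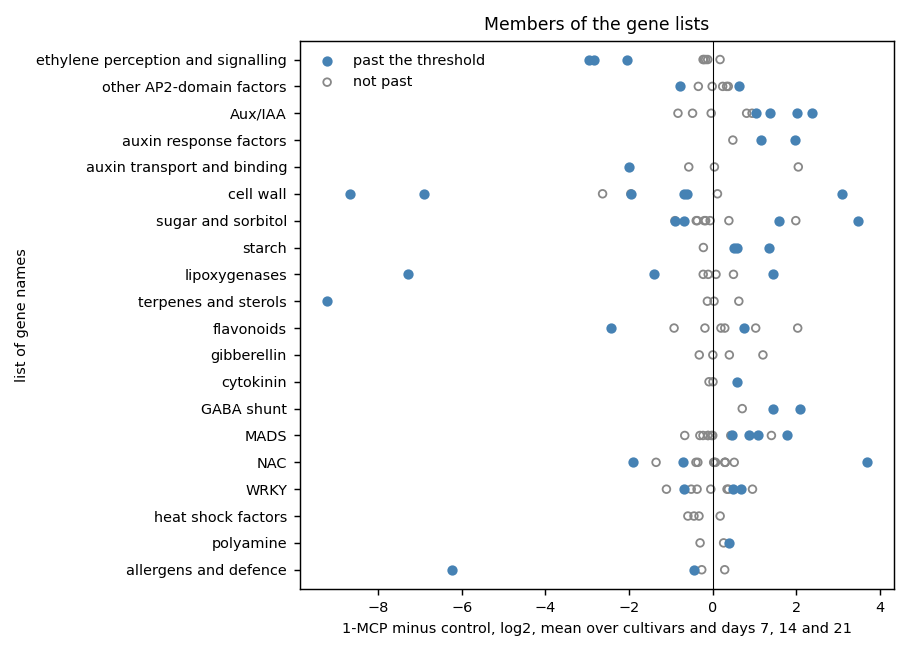
Each point is 1 gene of a list, placed by its log2 difference between 1-MCP and control fruit, averaged over cultivars and days 7, 14 and 21 (horizontal axis), with filled points past the threshold. The cell wall list holds 5 lower and 1 higher filled points, and the Aux/IAA list 4 higher ones.

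The effect of 1-MCP was already present at day 1 and had widened by day 7. At day 1 the receptor ETR2, a NAC factor, a beta-galactosidase and phytoene synthase had fallen and a cyclin had risen. At 2 months the fall of AFS1, LOX7a and ETR2 persisted. By then ACO1 was high in treated Golden Delicious and Granny Smith fruit.

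At day 1, 1799 entries differed across the 3 cultivars (940 higher, 859 lower), of which 175 and 246 did so at least 2-fold. The count was 6470 at day 7 (3537 higher, 2933 lower), 5179 at day 14 (2784 and 2395), 3482 at day 21 (1938 and 1544) and 1718 at 2 months (917 and 801). At 2 months the excess of higher calls turned around with centred differences (759 higher, 835 lower). It did so too without Granny Smith (4 and 18) or Fuji (74 and 154), but not without Golden Delicious (796 and 776). At day 1 it turned around whichever cultivar was left out. Per cultivar and without a test, at least 2-fold higher entries at day 1 numbered 819 in Golden Delicious, 865 in Granny Smith and 536 in Fuji, and at day 14 they numbered 2621, 3101 and 2596. With 4 added to the values these fell to 305, 298 and 138 at day 1 and to 1706, 2101 and 1676 at day 14, and the stricter filter left 481, 489 and 281 at day 1. At 2 months they numbered 2947, 2004 and 2026, or 1833, 1162 and 1163 with 4 added, more than at day 1 in each cultivar. The number of calls also depends on the spread between cultivars, so its fall by 2 months does not show a smaller effect. Effects correlated across entries, which are not independent replicates, at 0.42 to 0.45 between cultivars at day 1, at 0.67 to 0.72 at day 7 and at 0.53 to 0.64 at 2 months. With 1 cultivar left out, counts fell to as few as 491 at day 1, 2690 at day 7 and 1738 at day 14 without Golden Delicious, 323 at day 21 without Fuji and 22 at 2 months without Granny Smith. Without the filter on low values they were 1552 at day 7, 402 at day 14 and 1 at day 21.

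**Figure D3:**
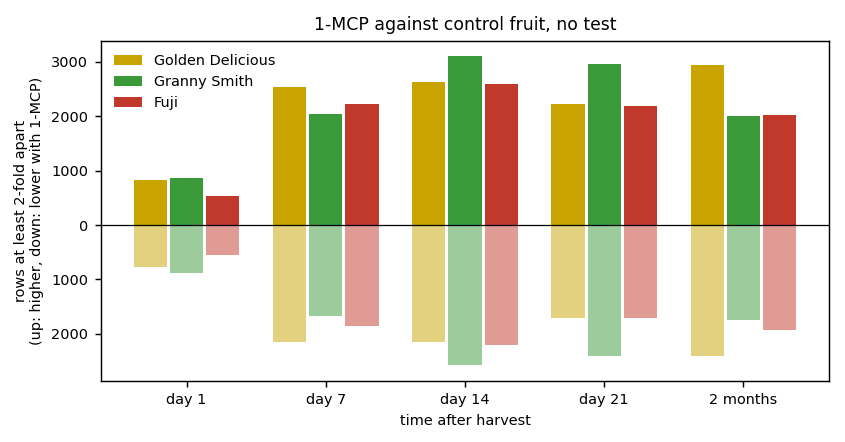
Number of transcript entries at least 2-fold higher (upward bars) or lower (downward bars) in 1-MCP than in control fruit at 5 times after harvest, by cultivar, without a test. The bars grow after day 1, from 819 to 2536 higher entries at day 7 in Golden Delicious, or from 305 to 1607 with 4 added to the values.

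ETR2 was lower at day 1 (-2.71, SE 0.2, adjusted p 0.00745), as were NAC1 (-3.04, SE 0.255, adjusted p 0.0129), BGAL101 (-1.93, SE 0.06, adjusted p 1.13e-05), SCL5 (-1.78, SE 0.121) and PSY2 (-1.30, SE 0.075, adjusted p 0.000144). CYCD3 was higher by 1.93 (SE 0.295, adjusted p 0.00995) and IAA11 by 1.60 (SE 0.308, adjusted p 0.0307). IAA4 was lower at day 1 (-0.35, adjusted p 0.0413), opposite to its rise at later days. ACO1 was not called at day 1 (-0.17, adjusted p 0.585), nor were AFS1 (-2.10, adjusted p 0.123), LOX7a (-3.41, adjusted p 0.108) and MALD1 (adjusted p 0.993). At 2 months AFS1 was lower (-8.52, SE 0.21, adjusted p 0.00058), as were LOX7a (-7.78), XET01 (-7.16), SCL5 (-3.84), ETR2 (-3.57, SE 0.12, adjusted p 0.000689), BGAL101 (-2.71) and MALD1 (-2.27). GBSSIa was higher by 1.74, AMY10 by 1.62, XET02 by 1.27 and IAA12 by 0.96. ACO1 missed the threshold at 2 months (-2.50, adjusted p 0.0675), with levels in 1-MCP fruit of 14.13 in Golden Delicious, 14.59 in Granny Smith and 10.41 in Fuji against 16.12, 15.88 and 14.65 in control fruit. PG1 at 2 months stood at 9.74 with 1-MCP and 9.96 in control fruit of Golden Delicious, and at 4.34 and 10.81 in Granny Smith. IAA4 (0.16, adjusted p 0.64) and PSY2 (-1.11, adjusted p 0.0762) were not called at 2 months. Without the filter on low values limma called 0 entries at day 1 (5041 at an unadjusted p under 0.05) and 0 at 2 months (5985), so none of these calls held there.

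Control fruit changed after harvest, and 1-MCP opposed part of that change. MALD1 rose and XET02 and IAA4 fell in control fruit by day 21. Genes that moved after harvest in 2 cultivars had a median response to 1-MCP of the opposite sign in the remaining one. With an estimated correlation, camera gave an unadjusted p under 0.05 for 3 of 6 sets. Treated fruit also departed from harvest, in ETR2 and PSY2 downward and in DAM2 and SUT1 upward.

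The control time course was called for 8788 of 20999 entries, against at most 8108 when times were shuffled within cultivars, and for 3857 without Golden Delicious, 5759 without Granny Smith and 3018 without Fuji. At day 21 against harvest, 693 entries rose and 1173 fell in control fruit of the 3 cultivars, 1866 in all, and 2648 rose and 2438 fell in 1-MCP fruit, 5086 in all. The control count was 0 by limma without Golden Delicious, with 4614 entries at an unadjusted p under 0.05, and that for 1-MCP fruit was 1153 without Fuji. The excess of risers in 1-MCP fruit turned around with differences centred on their median (2071 higher, 2790 lower). It also turned around whichever cultivar was left out. Without the filter on low values limma called 0 entries for control (6791 at an unadjusted p under 0.05) and 0 for 1-MCP fruit (8074), so none of the gene calls against harvest held there. At least 2-fold changes from harvest to day 21, counted per cultivar without a test, numbered 5571 in control and 5048 in 1-MCP fruit of Golden Delicious, 6318 and 3823 in Granny Smith, and 4391 and 4358 in Fuji. In control fruit MALD1 rose by 3.95 (SE 0.171, adjusted p 0.0061), HD1 by 2.23, ARF1 by 1.67, ERF1 by 1.44 and MYB111 by 1.31. SPL2 fell (-3.85), as did XET02 (-3.37, SE 0.422, adjusted p 0.0245), CAMTA1 (-2.58), IAA4 (-1.64) and MADS7 (-1.22). ACO1 (4.26, SE 1.257, adjusted p 0.101) and AFS1 (7.53, SE 1.551, adjusted p 0.054) were not called. ACO1 at harvest already stood at 13.17 in Golden Delicious and 11.77 in Fuji against 5.67 in Granny Smith. In 1-MCP fruit at day 21 ETR2 was below harvest (-2.51, SE 0.132, adjusted p 0.00114), as were PSY2 (-2.32) and omt5 (-2.05), while DAM2 had risen by 1.99, ARF1 by 1.98, ALF6 by 1.77, IAA12 by 1.62, CYCD3 by 1.36 and SUT1 by 0.93.

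Sets of entries at least 2-fold up or down at day 21 in control fruit of the other 2 cultivars were then followed in each cultivar. The 1118 entries that rose elsewhere stood at a median of 1.14 over harvest in Golden Delicious control fruit at day 21, and their median difference between 1-MCP and control fruit was -0.87, with 81% of them opposed. For the 1031 entries followed in Granny Smith the medians were 1.47 and -0.42 (65.6% opposed), the latter -0.65 with the stricter filter and -0.68 with 4 added, and for the 1121 in Fuji 1.17 and -0.51 (73%). The sets that fell elsewhere held 1598, 1591 and 1773 entries, with medians against harvest of -1.99, -2.22 and -1.58 and responses to 1-MCP of 0.87, 0.84 and 0.84. By camera with the preset correlation each set shifted (p 4.2e-16 in Fuji for the set that fell and 1.32e-06 or smaller in all). With an estimated correlation the camera p was under 0.05 for the Fuji sets (p 0.0141 and 0.00967) and for the Golden Delicious set that fell (0.0413). It was not for the remaining Golden Delicious set (0.0666) or for Granny Smith (0.247 and 0.186). None of these camera p-values was adjusted over the sets, and 0.0413 lay near the threshold. Control fruit at days 7, 14 and 21 had more entries listed at 0, up to 18.7% in Granny Smith at day 14, than 1-MCP fruit there (15.6%).

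**Figure D4:**
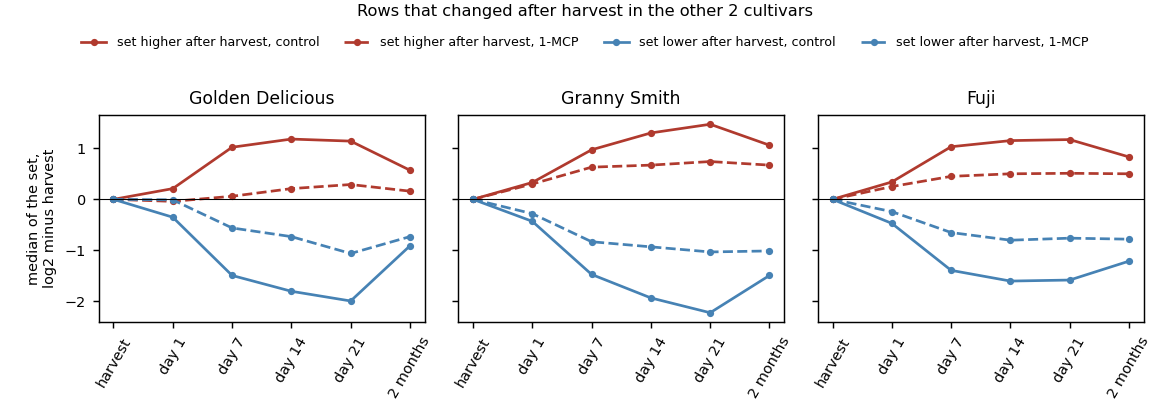
Median log2 change from harvest (vertical axis) over time in control (solid) and 1-MCP fruit (dashed), in each cultivar, of sets that rose (red) or fell (blue) by day 21 in control fruit of the other 2 cultivars. In every panel the dashed lines lie nearer 0 than the solid ones at day 21, as in Golden Delicious with 0.29 against 1.14.

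The cultivars shared most of the response and differed in part. The cyclin CYCD3 and the auxin gene IAA4 rose more in Golden Delicious than in Fuji. The sorbitol enzyme gene S6PDH was higher with 1-MCP in Golden Delicious and, at days 7 and 14, lower in Granny Smith, and NAC10 rose more in Golden Delicious. A dehydrin responded differently in Golden Delicious and Fuji.

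Within cultivars, with days as the unit, 17848 of 42396 entries were called in Golden Delicious (9601 higher, 8247 lower), 16706 in Granny Smith (8975 and 7731) and 9279 of 20999 in Fuji (4924 and 4355). Mean effects correlated across entries at 0.75 to 0.77 between cultivars. The 1-MCP effect differed between Golden Delicious and Granny Smith for 1699 of 42396 entries, between Golden Delicious and Fuji for 1590 of 20999 and between Granny Smith and Fuji for 1426. Of these, 742, 561 and 566 had effects of opposite sign. Without day 14 limma called 2595 entries in Golden Delicious, 4634 in Granny Smith and 5266 in Fuji, and the differences numbered 0 (4158 at an unadjusted p under 0.05), 217 and 288; without day 7 the difference between Golden Delicious and Granny Smith rose to 5755 entries. Without the filter on low values limma called 8038, 4420 and 4459 entries within the cultivars and 0 differences for each pair (9738, 5143 and 4866 at an unadjusted p under 0.05), so no gene's difference between cultivars held there.

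S6PDH (NM_001294028), a sorbitol-6-phosphate dehydrogenase, had the largest difference of a named gene, 6.40 between Golden Delicious and Granny Smith (SE 0.617 over 3 days, adjusted p 0.0196). In Golden Delicious its level in control fruit was 8.01, 4.56 and 4.51 at days 7, 14 and 21 against 11.13, 11.17 and 10.35 with 1-MCP. In Granny Smith the levels were 13.22, 11.92 and 9.51 in control against 10.39, 10.36 and 10.28 in 1-MCP fruit. Levels in 1-MCP fruit were thus alike in both cultivars (10.28 to 11.17), and the difference lay mainly in control fruit. The response of NAC10 was higher by 3.61 in Golden Delicious than in Granny Smith, and that of FPPS, a farnesyl pyrophosphate synthase, lower (-1.79). CYCD3 responded more in Golden Delicious (2.45) and in Granny Smith (2.39) than in Fuji. The responses of IAA11 (1.52), IAA4 (1.43) and GAD1 (1.01) were higher in Golden Delicious than in Fuji, and that of the dehydrin was lower (-3.39). The dehydrin was not called across the 3 cultivars (-1.88, adjusted p 0.101). With days as the unit it fell (-3.21 in Golden Delicious and -2.59 in Granny Smith), against 0.18 in Fuji (adjusted p 0.641), although the difference between Granny Smith and Fuji was not past the threshold (-2.77, adjusted p 0.109). Its level at 2 months was 13.13 to 14.31 in every group, treated or not.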

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

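The tests weighing the S6PDH pattern were chosen after the result was seen, and the tests over changed signs were planned before their counts were seen. Each gene given here stood out because its response to 1-MCP differed between cultivars, by limma on the difference with days 7, 14 and 21 as the unit.

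Between Golden Delicious and Granny Smith the response was higher in Golden Delicious for S6PDH by 6.404 (SE 0.617, adjusted p 0.0196), NAC10 by 3.614 (SE 0.321), SOT2 by 2.274 (SE 0.171), pp2-1 by 2.237 (SE 0.235) and MYB30 by 1.782 (SE 0.136). It was lower in Golden Delicious for NAC4 (-1.935, SE 0.263), FPPS (-1.792, SE 0.293), LAR1 (-1.718, SE 0.197), MdTCP2B (-1.57, SE 0.208) and HB1 (-1.5, SE 0.29). Adjusted p for the remaining genes of this pair ranged from 0.00484 for SOT2 to 0.0454 for HB1.

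Against Fuji the response in Golden Delicious was higher for CYCD3 by 2.454 (SE 0.439, adjusted p 0.0162), IAA11 by 1.523, IAA4 by 1.427, GAD1 by 1.008 and PSY2 by 0.887. For PSY2 this means a smaller fall in Golden Delicious than in Fuji. It was lower in Golden Delicious for the dehydrin (-3.387, SE 0.446, adjusted p 0.0336), COL9 (-1.415), omt5 (-1.158), CIPK22 (-1.105) and NAC1 (-0.907). The response in Granny Smith was higher than in Fuji for CYCD3 by 2.39 (SE 0.437, adjusted p 0.0166), FPPS by 1.928, ALF6 by 1.168, PSY2 by 0.901 and OSC1 by 0.893. It was lower in Granny Smith for omt5 (-1.819), pp2-3 (-1.592), SCL5 (-1.362), MdSOT4 (-1.052) and CIPK27 (-0.976). The largest adjusted p among these was 0.0418, for ALF6. Without the filter on low values limma called 0 differences for each pair (9738, 5143 and 4866 at an unadjusted p under 0.05), so none of these calls held there. Without day 14 limma called 0 differences between Golden Delicious and Granny Smith (4158 at an unadjusted p under 0.05), so no call of that pair held. The pairs with Fuji then had 217 (Golden Delicious) and 288 (Granny Smith) calls, and whether the genes given here were among them was not examined.

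S6PDH was higher in 1-MCP than in control fruit of Golden Delicious and, at days 7 and 14, lower in Granny Smith. Its levels in 1-MCP fruit were alike in both cultivars, and the difference lay mainly in control fruit. A swap of treated and control columns in Golden Delicious would turn around every gene, yet over 1088 entries at least 2-fold lower with 1-MCP in Granny Smith and Fuji the median in Golden Delicious was -1.63. Values near the floor are argued against by a Golden Delicious difference of 5.03 with 4 added to every value. The lowest day in Golden Delicious lay 2.36 above the highest day in Granny Smith, but this restates how the gene was picked and does not test a difference between the cultivars, which stays open. A difference between the fruit lots of treated and control fruit within a cultivar was not tested and stays open.

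For the tests with 3 units, the signs of the units were changed in all 4 ways, and the real signs, which count as 1 of the 4, gave the highest count each time, with 0 as the highest of the other ways. The real counts were 7214 for the mean of days 7, 14 and 21 across cultivars, 1799 at day 1, 6470 at day 7, 5179 at day 14, 3482 at day 21 and 1718 at 2 months. They were 1866 for control and 5086 for 1-MCP fruit at day 21 against harvest, 17848 in Golden Delicious, 16706 in Granny Smith and 9279 in Fuji over days. For the cultivar differences they were 1699, 1590 and 1426. With 4 ways the share is too large to come under 0.05. For the control time course, 1 of 100 arrangements of the times within cultivars, the real one, gave 8788 calls, and the highest other gave 8108. The real order thus ranked first, which does not exclude chance for the calls themselves. The other arrangements thus call nearly as many entries; why they do was not tested, and the count of 8788 by itself is no measure of how many entries changed.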

How the results depend on the processing

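All alternatives given here were chosen after the tables were seen to hold group means. No paired analysis was possible because the columns are group means and carry no replicate numbers; this concerns pairing by replicate, since differences were taken within cultivars and days throughout. Settings named in advance and not run for the same reason were the replicate block, leaving out each library, median-ratio size factors, a pseudocount of 0.1 and fits with the libraries of the compared groups alone. The depth is unknown, so what it limits could not be assessed.

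Single named genes were rerun if they had Fuji values, and for the mean of days 7, 14 and 21 alone; genes without Fuji values, other contrasts per gene and 2-fold counts against harvest were not rerun. Among the genes rerun no called direction reversed. Calls were lost for 3 with 4 added to the values, 6 without a filter, 6 without day 7, 2 without day 14, 17 without Fuji, 14 without Golden Delicious and 15 without Granny Smith. Calls were gained for 2 without Granny Smith and for 1 each without Fuji, day 14 or day 21 and with the stricter filter. ACO1, AFS1, LOX7a, MALD1, ETR2, PSY2, NAC1, LOX5a, XET02, IAA4, SUT1, DAM2 and GABA-T2 kept their calls for that mean in every alternative run.

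Without a filter, limma called across cultivars 0 entries at day 1 (5041 at an unadjusted p under 0.05), 1552 at day 7, 402 at day 14, 1 at day 21 and 0 at 2 months (5985 unadjusted). It called 0 for control (6791) and 0 for 1-MCP fruit (8074) at day 21 against harvest. Over days it called 8038 in Golden Delicious, 4420 in Granny Smith, 4459 in Fuji and 617 of the entries in 2 tables, and 0 cultivar differences for each pair (9738, 5143 and 4866 unadjusted). Without a filter 1611 of 27170 entries had no spread at all at day 1, against 17 of 20999 kept. The prior degrees of freedom of limma dropped there to 0.557 from 5.57. Both went along with the loss of calls at day 1, but the cause was not tested there or elsewhere.

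With cultivar-by-day pairs as the unit the mean of days 7, 14 and 21 gave 12643 calls, with more units by construction. With 2 cultivars as the unit the entries in 2 tables gave 3452; this also replaced the rule of passing in both cultivars by 1 test, and the cause was not tested. Adding 4 on the linear scale draws low values together, and it lowered counts of at least 2-fold differences. For Golden Delicious, Granny Smith and Fuji these became 2545, 2853 and 2399 in the mean, 618, 658 and 360 at day 1, 3021, 2131 and 2516 at day 7, and 2347, 3573 and 2402 at day 21. At day 14 they became 3155 in Golden Delicious and 3121 in Fuji, and at 2 months 2269 in Granny Smith and 2413 in Fuji. The stricter filter, which tests fewer entries, gave 974, 1043 and 649 at day 1. The response of the set higher after harvest elsewhere moved in Granny Smith from -0.42 to -0.65 with the stricter filter and to -0.68 with 4 added, and the cause was not tested.

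Leaving out 1 cultivar or day gave, across cultivars, 2166 (without Fuji) to 7498 (without day 21) calls for the mean. The range was 491 (without Golden Delicious) to 923 (without Granny Smith) at day 1, 2690 to 4304 at day 7 with the same omissions, 1738 (without Golden Delicious) to 2364 (without Fuji) at day 14, 323 (without Fuji) to 1620 (without Golden Delicious) at day 21, and 22 (without Granny Smith) to 1572 (without Golden Delicious) at 2 months. At day 21 against harvest it was 0 by limma (without Golden Delicious, 4614 unadjusted) to 844 (without Granny Smith) for control fruit and 1153 (without Fuji) to 3459 (without Granny Smith) for 1-MCP fruit. The control time course gave 3018 (without Fuji) to 5759 (without Granny Smith). Over days, from without day 14 to without day 7, the ranges were 2595 to 14455 in Golden Delicious, 4634 to 17526 in Granny Smith, 5266 to 7469 in Fuji and 734 to 4917 for the entries in 2 tables. For the differences they were 0 by limma (4158 unadjusted) to 5755 between Golden Delicious and Granny Smith, 217 to 1917 between Golden Delicious and Fuji, and 288 to 2270 between Granny Smith and Fuji. Fewer units explain lower counts in part; the cause of the higher ones without day 7 was not tested. Apart from values inside these ranges, the remaining counts stayed within 1.5 times their value.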

Other observations

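The tests of shares in this part were planned before their results were seen, and no test in this part was chosen afterwards. The idea tested was that 1-MCP held genes near their harvest level. For the 1603 entries at least 2-fold higher with 1-MCP across cultivars, the mean of days 7, 14 and 21 lay nearer harvest in 1-MCP than in control fruit for 56.8% in Golden Delicious, 74.9% in Granny Smith and 55.5% in Fuji. The median stood at 0.65, 0.21 and 0.61 over harvest in 1-MCP fruit and at -1.11, -1.54 and -0.9 in control fruit. The idea required more than 50% in each cultivar, and the lowest share, 55.5%, met this. Yet 49.3% of these entries in Golden Delicious, 34.6% in Granny Smith and 45.4% in Fuji stood at least 2-fold from harvest in 1-MCP fruit, against 55.7%, 68.4% and 49.3% in control fruit. Holding at harvest level may thus account for some of the higher genes, and for many of them it does not.

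For the 1218 entries at least 2-fold lower with 1-MCP the idea failed. The share nearer harvest in 1-MCP fruit was 71.8% in Granny Smith, 49.8% in Fuji and 36.2% in Golden Delicious. Their median in 1-MCP fruit was -1.18 against harvest in Golden Delicious, -0.32 in Granny Smith and -0.88 in Fuji, while control fruit stood at 0.58, 1.49 and 0.87. In Golden Delicious, where ACO1 was already high at harvest (13.17), many of these entries thus dropped under their harvest level with 1-MCP. A harvest point later in ripening for Golden Delicious than for Granny Smith could give the low 36.2%, which no value here tests.

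Levels of the dehydrin at 2 months, after 4.84 to 9.79 in control fruit at day 21, were 13.52 in Golden Delicious, 13.13 in Granny Smith and 14.31 in Fuji control fruit. With 1-MCP they were 14.12, 13.40 and 14.05.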
